A study of Mus musculus with 6 samples.

How the data were processed

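Poly(A)-selected RNA of dendritic cells from the spleens of *Ldlr*-deficient mice was sequenced in 6 libraries, 2 each for chow-fed mice and for lipid-free and lipid-laden cells of mice fed the western-type diet for 3 weeks. Per the labels' protocols, total RNA with an RNA integrity number of at least 6.4 was treated with DNase, made into NEBNext Ultra libraries and sequenced as single reads of 80 bp on an Illumina NextSeq instrument. The protocols do not state that the libraries mark strand, and how cells were sorted into lipid-free and lipid-laden is not given in the sources used here. Per the submitters' processing notes, FastQC, Bowtie2, TopHat2, SAMtools and HTSeq were used with the mm10 build. Tool versions, the gene annotation and the strand setting are not given in the sources used here. The authors deposited whole-number read counts per gene symbol, without normalization and with 1 column per library. Each column was matched to its sample by name, and no column was left unmatched.

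The table held 24421 genes, of which 4177 had no counts in any library, and every line named a gene. The range of total counts was 10999482 to 12993812, and 12987 to 17899 genes had counts. A floor of 3 counts per library, the upper limit a count of 0 allows, was 0.181 to 0.34 CPM, where CPM are counts scaled to the effective library size. No molecular identifiers are mentioned in the protocols, and floors cover counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 82.8 in chow, 31.9 in lipid-free and 79.6 in lipid-laden libraries. The first principal component held 63.7% of the variance and the second 19.5%. No sequencing batch or date is given in the labels.

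Groups came from the labels. Before the data were examined, the comparisons, tests, 35 gene lists, the naming rule and all alternatives apart from the offset were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr at a minimum count of 10, TMM normalization and a robust quasi-likelihood fit of all 6 libraries with group means, so that the 3 groups shared 1 estimate of the spread. Two-sided p-values were adjusted by the Benjamini-Hochberg method over 12107 tested genes in each of 3 comparisons, with a threshold of 0.05. The common biological coefficient of variation was 0.313. Values after ± are standard errors of log2 fold changes with 2 libraries per group. Gene lists, of lipid handling, immune function, stress, cell cycle and spleen cell types, were tested with camera from limma 3.58.1 at a preset correlation of 0.01. List p-values were adjusted over the 33 lists with at least 5 tested members, and camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone used the p-values of its tested members. Tables were handled and figures drawn in Python 3.11.15 with matplotlib 3.10.9.

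The naming rule took the 12 called genes with the highest and the 12 with the lowest log2 fold change per comparison, with both libraries of a group above both of the other. It added up to 4 called members of each list and a fixed panel of genes of lipid handling, activation and cell type, whatever their result. The panel is given in full. Among the other genes of the rule, those given were chosen for length with their values in view. Coordinates are of mm10 from GENCODE M21, which held 23376 of the symbols. GC content and length were available for 96.3% of tested genes. Of 102 named genes, 30 have exons that overlap another gene, 25 of them on the opposite strand, and their counts may include reads of that gene. *Hspa1a*, *Hspa1b*, *Oas1a*, *Clec4a4* and *Ifi205* have close paralogs whose reads the counting could split.

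Alternatives were RLE size factors, library size alone, no filter and a minimum count of 30, a fit without the robust prior, DESeq2 1.42.0, limma-voom, a fit of only the 4 libraries compared, the replicate number as a block, and each library left out in turn. An offset for GC content and length was added after the data were examined: per library, a spline with 5 degrees of freedom of the log2 deviation on each property was taken out. The pipeline was tested on simulated counts of 12107 genes with 200 genes changed by known folds. Without GC bias it recovered 79%, 83% and 76% of 4-fold changes, with 2, 1 and 5 false calls, in lipid-laden against lipid-free, lipid-laden against chow and lipid-free against chow. With a simulated GC bias there were 363, 355 and 289 false calls without the offset and 1, 2 and 4 with it. That bias was a smooth function of the same GC values the offset fits, and alike in both libraries of a group. Its removal was therefore built in and does not show how well the offset works on these data. A list raised 2-fold in simulated lipid-laden libraries was the only list past the threshold. That simulation drew genes independently and without GC bias, so it does not show how often camera calls lists of correlated genes falsely.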

Results

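Gene expression was measured by poly(A)-selected RNA-seq in dendritic cells from the spleens of mice lacking the low-density lipoprotein receptor, a strain that develops high blood cholesterol on a western-type diet. Dendritic cells take up antigen and present it to T cells, and their 2 classical subsets are called cDC1 and cDC2. The series title names splenic cDC2s, while the sample labels say only dendritic cells. The 6 libraries formed 3 groups of 2: cells from chow-fed mice, and lipid-free and lipid-laden cells from mice given the western-type diet for 3 weeks. Total counts over genes were 12993812 and 10999482 in the chow libraries, 11398449 and 11343495 in the lipid-free libraries, and 11825810 and 12601540 in the lipid-laden libraries. Of 24421 genes in the table, 12107 had enough counts to be tested. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

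*Ldlr*, the deleted receptor gene (chromosome 9, 21723483 to 21749919 of mm10), had counts in every library: 88.3 and 47.5 CPM (counts scaled to the effective library size) in chow, 81.4 and 67.1 in lipid-free and 26.6 and 34.6 in lipid-laden libraries. No library came from an animal with the intact gene, and counts over the whole gene do not separate intact from disrupted transcripts, so these values check no label. *Ldlr* was lower in lipid-laden than in lipid-free libraries (log2 fold change -1.28 ± 0.37, SE; edgeR adjusted p = 0.0185). That call was lost with the offset for GC content and length described next (adjusted p = 0.0527), with scaling by library size alone (0.251), without lipid-free replicate 1 (0.0755) and without lipid-laden replicate 1 (0.0968).

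The libraries also differed in a property of the genes themselves. A library's deviation from the mean over libraries followed gene GC content, with rank correlations across genes, which are not independent replicates, of -0.62 and 0.07 in chow, 0.61 and 0.71 in lipid-free, and -0.47 and -0.47 in lipid-laden libraries. The ribosomal RNA precursor gene *Rn45s* took 6.41% and 9.19% of counts in chow, 10.7% and 15.3% in lipid-free, and 3.21% and 2.05% in lipid-laden libraries. Each comparison was therefore also fitted with an offset for gene GC content and length, an alternative added after seeing the data.

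Lipid-laden and lipid-free cells of the same diet were compared first, the contrast closest to the lipid loading that the series title names. The mean log2 CPM of cDC1 markers was 8.60 and 8.62 in lipid-laden and 3.84 and 4.15 in lipid-free libraries. Lipid load and cell subset therefore cannot be told apart in any gene or list compared below between these groups. The largest coherent difference lay in subset markers. Of 16 tested cDC1 markers, 14 were higher in lipid-laden libraries and none was lower, with a median log2 fold change of 4.98, and 15 were higher when adjusted over the list alone. *Xcr1*, the chemokine receptor that marks cDC1 (chromosome 9, 123852315 to 123862029), stood at 509 and 476 CPM in lipid-laden against 2.42 and 4.59 CPM in lipid-free libraries, a log2 fold change of 7.14 ± 0.43. The double-stranded RNA sensor *Tlr3* (chromosome 8, 45395665 to 45411080), the adhesion molecule *Cadm1* and *Hepacam2* changed by 7.06 ± 0.52, 5.59 ± 0.35 and 5.74 ± 0.42, and edgeR adjusted p for these 4 genes was at most 3.09e-05. Of 16 tested cDC2 markers, 13 were lower and 1 higher, with the same counts adjusted over the list alone and a median of -3.13. *Sirpa*, the inhibitory receptor used to sort cDC2 (chromosome 2, 129592835 to 129632228), fell from 1039 and 1272 CPM to 56.9 and 73.7 CPM (log2 fold change -4.15 ± 0.38). *Esam*, *Cd4* and *Clec4a4*, surface molecules of the Notch-dependent cDC2 of the spleen, changed by -3.09 ± 0.33, -3.62 ± 0.39 and -3.32 ± 0.37, and the Notch target *Dtx1* by -5.45 ± 0.37, with edgeR adjusted p of at most 0.0002.

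**Figure D1:**
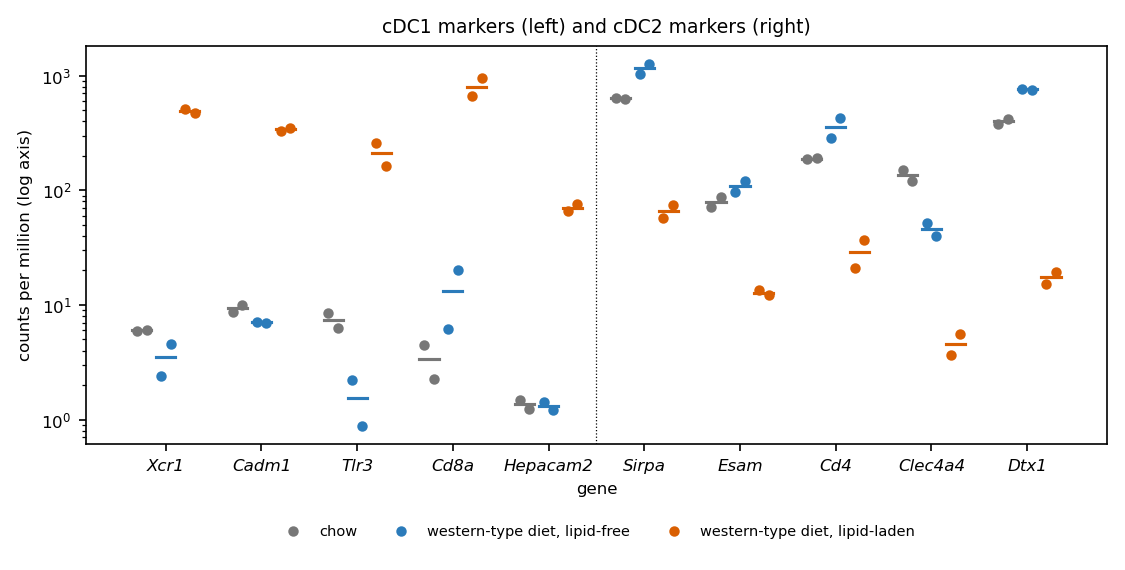
CPM (log axis) of 5 cDC1 markers, left of the dotted line, and 5 cDC2 markers, right of it, in the 6 libraries. Points are libraries and bars are group means. *Xcr1* lies at 509 and 476 CPM in the lipid-laden libraries and at or below 6.01 CPM in the other libraries.

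Both classes of cDC2 markers went the same way. The lists are not independent: 9 of 16 cDC2, 5 of 11 ESAM-high and 6 of 12 ESAM-low tested members also stood in other lists. Of 11 tested markers of ESAM-high cDC2, 8 were lower and 1 higher (9 lower and 1 higher when adjusted over the list alone). These included the transcription factor *Tbx21* (-3.86 ± 0.36) and the matrix metalloproteinase *Mmp9* (-7.62 ± 0.63). Of 12 tested markers of ESAM-low cDC2, 8 were lower and 2 higher under both adjustments, among them the colony-stimulating factor receptor *Csf1r* (-3.69 ± 0.36). The transcription factor *Zbtb46*, which both classical subsets express, stood at 110.4 and 71.1 CPM against 63.9 and 58.6 CPM (log2 fold change 0.57 ± 0.38, edgeR adjusted p = 0.246). Other genes among those with the lowest fold changes were transglutaminase *Tgm2* (-6.88 ± 0.41), *Cd101* (-6.77 ± 0.43) and the sialic acid receptor *Siglece* (-6.48 ± 0.42). Exons of *Tgm2*, *Csf1r* and *Tlr3* overlap other genes on the opposite strand, so that part of their counts may be shared. Among those with the highest was *Ifi205* (8.83 ± 0.59), whose reads may be shared with near-identical members of its gene family. The receptor tyrosine kinase *Met* (chromosome 6, 17463800 to 17573980) had no counts in either lipid-free library and 55.6 and 44.3 CPM in lipid-laden libraries, at least 159-fold higher against a floor of 3 counts per library. *Homer2*, also without counts in the lipid-free libraries, was at least 43.7-fold higher. The cDC1, cDC2, ESAM-high and ESAM-low lists passed the set test (camera adjusted p = 6.11e-25, 6.62e-09, 2.46e-09 and 0.00141). With an estimated correlation the adjusted p was 0.0473, 0.114, 0.111 and 0.665, so that the cDC1 call alone held. The estimated correlations were -0.0005, 0.022, -0.037 and 0.214. Those of the cDC1 and ESAM-high lists lay below the preset one. The weaker p-values of these lists therefore do not reflect more correlation among their genes. They came with the change of test setting alone, on the same values, and so do not measure a smaller difference. In the fit with the GC and length offset the cDC1 and cDC2 medians were 4.04 and -2.72. Both lists passed there at the preset correlation (camera adjusted p = 3.49e-33 and 6.75e-12). With the offset and an estimated correlation, camera adjusted p was 0.149 for both.

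*Plin2*, which coats lipid droplets (chromosome 4, 86648386 to 86670060), was at 143 and 199 CPM in lipid-laden and 55.3 and 49.8 CPM in lipid-free libraries (log2 fold change 1.70 ± 0.41, edgeR adjusted p = 0.00874). The fatty acid and lipoprotein receptor *Cd36* (chromosome 5, 17781690 to 17888801) was at 227 and 250.3 against 3.83 and 0.765 CPM (log2 fold change 6.68 ± 0.62). The mitochondrial fatty acid dehydrogenase *Acadl* and the elongase *Elovl6* were higher (1.71 ± 0.31 and 3.82 ± 0.64), while their list mates *Acadvl* (-1.13 ± 0.33), a long-chain dehydrogenase, the nuclear receptor *Ppard* (-1.41 ± 0.34), the elongase *Elovl1* (-1.13 ± 0.33) and the citrate carrier *Slc25a1* (-1.16 ± 0.39) were lower. In full, of 19 fatty acid oxidation genes 2 were higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.628) and of 10 fatty acid synthesis genes 2 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.650). The fatty acid carrier *Fabp5*, the lipoprotein receptor *Lrp1*, the scavenger receptor *Cd68* and the hormone-sensitive lipase *Lipe* were lower (-3.00 ± 0.40, -2.74 ± 0.37, -1.98 ± 0.33 and -1.38 ± 0.32). The edgeR adjusted p for these 12 genes was at most 0.0342. Of 16 tested lipid droplet genes, 2 were higher and 4 lower (3 higher and 4 lower when adjusted over the list alone). Of 15 lipid uptake genes, 2 were higher and 4 lower (1 higher and 4 lower when adjusted over the list alone), and neither list passed the set test (camera adjusted p = 0.358 and 0.127). Of 12 targets of the oxysterol receptor LXR and genes of cholesterol efflux, 5 were lower under both adjustments and none higher (camera adjusted p = 0.0277, and adjusted p = 0.665 with an estimated correlation). These included the phospholipid transfer protein *Pltp* (-4.79 ± 0.46) and the receptor gene *Nr1h3* (-3.67 ± 0.53), while the cholesterol exporter *Abcg1* stood at 149.6 and 147 against 129 and 131 CPM (edgeR adjusted p = 0.677). Exons of *Pltp* overlap those of the lysosomal gene *Ctsa* on the opposite strand, so their counts may be shared, and exons of *Acadvl* and *Elovl1* also overlap another gene on the opposite strand. Of 22 cholesterol synthesis genes, 6 were higher and 3 lower under both adjustments, and the list did not pass (camera adjusted p = 0.692). The isomerase *Idi1* was higher (2.89 ± 0.66), and the synthase *Hmgcs1* and the rate-limiting reductase *Hmgcr* changed by 2.10 ± 0.57 and 1.69 ± 0.45. The epoxidase *Sqle* was higher (2.01 ± 0.54) and the decarboxylase *Mvd* lower (-1.48 ± 0.33). The desaturase *Fads1* was higher (1.59 ± 0.38), and the triglyceride synthase *Dgat2* (-1.78 ± 0.42) and the lipogenic regulator *Srebf1* (-1.23 ± 0.31) were lower. *Abca1*, which exports cholesterol (0.33 ± 0.73), *Cpt1a*, which carries fatty acids into mitochondria (0.22 ± 0.31), and the lipoprotein lipase *Lpl* (-1.89 ± 1.02) did not pass (edgeR adjusted p = 0.737, 0.587 and 0.152). The call of *Acadvl* was lost when scaled by library size alone (adjusted p = 0.143), without lipid-free replicate 1 (0.0548), without lipid-free replicate 2 (0.108), without lipid-laden replicate 1 (0.0845) and with the offset (0.121). The call of *Elovl1* was lost when scaled by library size alone (adjusted p = 0.141), without lipid-free replicate 1 (0.0585), without lipid-free replicate 2 (0.106), without lipid-laden replicate 1 (0.0986) and with the offset (0.0643). The call of *Slc25a1* was lost when scaled by library size alone (adjusted p = 0.191), without lipid-free replicate 2 (0.135), without lipid-laden replicate 1 (0.178) and with the offset (0.854). *Dgat2*, *Mvd*, *Srebf1* and *Ppard* lost their calls when scaled by library size alone (adjusted p = 0.0526, 0.0641, 0.0937 and 0.11). *Fads1* and *Srebf1* lost their calls without lipid-free replicate 1 (adjusted p = 0.0509 and 0.0578). *Hmgcr* lost its call without lipid-free replicate 2 (adjusted p = 0.0572). *Hmgcr*, *Hmgcs1*, *Dgat2*, *Fads1*, *Sqle* and *Ppard* lost their calls without lipid-laden replicate 1 (adjusted p = 0.0886, 0.0816, 0.0708, 0.0648, 0.0801 and 0.0652). *Ppard* lost its call without lipid-laden replicate 2 (adjusted p = 0.051). *Hmgcr*, *Hmgcs1*, *Dgat2*, *Mvd* and *Srebf1* lost their calls with the offset (adjusted p = 0.0869, 0.114, 0.0684, 0.325 and 0.0585), *Lpl* passed (adjusted p = 0.0407), and *Abca1* turned to a log2 fold change of -0.73.

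**Figure D2:**
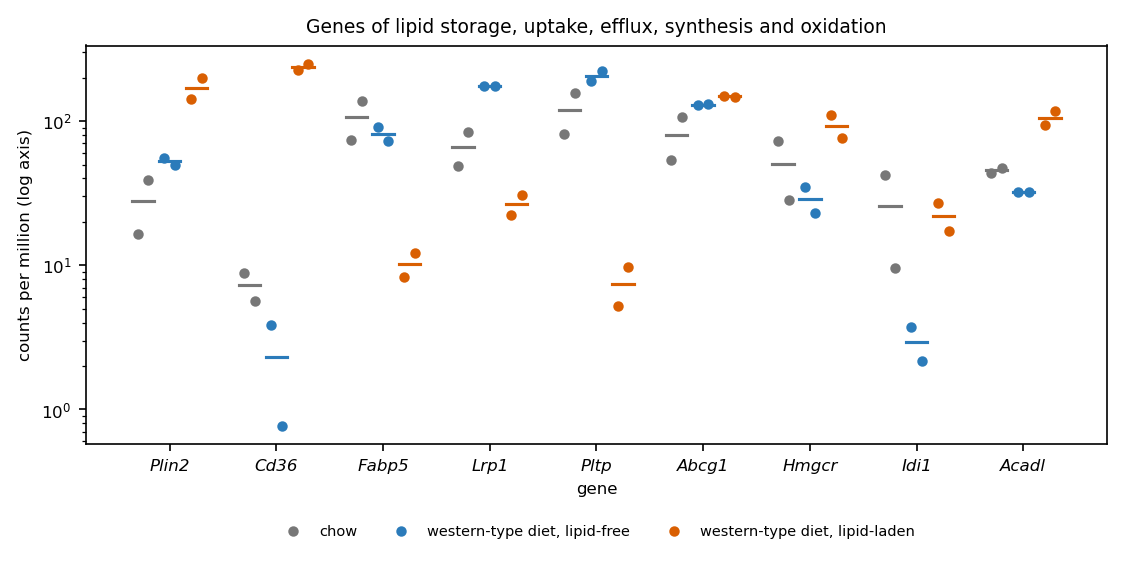
CPM (log axis) of 9 genes of lipid handling in the 6 libraries. Points are libraries and bars are group means. *Plin2* lies at 143 and 199 CPM and *Cd36* at 227 and 250.3 CPM in the lipid-laden libraries, above the other libraries.

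Of 25 lysosome genes, 12 were lower in lipid-laden libraries and 2 higher (3 higher and 13 lower when adjusted over the list alone), among them the transcription factor *Tfeb* (-3.01 ± 0.37) and the proteases *Ctsd* (-2.86 ± 0.39) and *Ctsa* (-2.85 ± 0.41). Of 13 genes of MHC class II presentation, 5 were lower and none higher under both adjustments, including *H2-DMb2* (-2.80 ± 0.40), the thiol reductase *Ifi30* (-2.24 ± 0.42) and *H2-Oa* (-2.60 ± 0.49). The class II chain *H2-Ab1* itself stood at 5487 and 11654 against 21825 and 22476 CPM (log2 fold change -1.37 ± 0.61, edgeR adjusted p = 0.0886). *H2-Ab1* passed without lipid-laden replicate 2 (adjusted p = 0.0304), in DESeq2 (0.00162) and in limma-voom (0.0399). Both lists passed the set test (camera adjusted p = 0.00821 and 0.000143), and both calls were lost with an estimated correlation (adjusted p = 0.665 for each).

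Activation genes moved in both directions. The costimulatory ligand *Cd86* was higher (3.25 ± 0.36), as were the cytokine gene *Il12b* (5.05 ± 0.59) and the chemokine gene *Cxcl9* (4.19 ± 0.44), while *Il1b* (-1.53 ± 0.30), the NF-kB subunit *Relb* (-2.62 ± 0.42) and the PD-1 ligand *Pdcd1lg2* (-2.69 ± 0.42) were lower, with edgeR adjusted p of at most 0.00356. The costimulatory receptor *Cd40* (-1.21 ± 0.31) and the transcription factor *Irf4* (-1.21 ± 0.33) were lower, and *Cd80* (0.86 ± 0.39), the migration receptor *Ccr7* (-0.37 ± 0.40) and *Tnf* (-0.83 ± 0.45) did not pass (edgeR adjusted p = 0.0969, 0.483 and 0.153). *Cd40* and *Irf4* lost their calls when scaled by library size alone (adjusted p = 0.0859 and 0.185), and *Cd80* passed (adjusted p = 0.0467). *Cd40* and *Irf4* lost their calls without lipid-free replicate 2 (adjusted p = 0.0749 and 0.13). *Irf4* lost its call without lipid-laden replicate 1 (adjusted p = 0.0922). *Cd80* and *Ccr7* turned with the offset to log2 fold changes of -0.48 and 0.36. Of 18 maturation genes 3 were higher and 6 lower, and of 15 inflammatory genes 3 were higher and 7 lower, with the same counts adjusted over the list alone. Neither list passed (camera adjusted p = 0.156 and 0.405), and the mean of the inflammatory list (0.14) and its median (-0.83) differed in sign. Of 27 type I interferon response genes, 15 were lower and 2 higher (3 higher and 15 lower when adjusted over the list alone), including the antiviral genes *Oas1a* (-5.04 ± 0.55), *Rtp4* (-4.02 ± 0.39) and *Oasl2* (-3.69 ± 0.35). The list passed (camera adjusted p = 9.32e-06) but not with an estimated correlation (adjusted p = 0.665). The endoplasmic reticulum chaperones *Hsp90b1* (3.33 ± 0.42) and *Hspa5* (2.43 ± 0.35) were higher, in a stress response list with 6 of 18 members higher and 2 lower under both adjustments that passed with the offset (camera adjusted p = 0.017) and not without it (0.379). With an estimated correlation and the offset its adjusted p was 0.377. Of 26 oxidative phosphorylation genes 7 were lower and 1 higher under both adjustments (camera adjusted p = 0.0193), and the call was lost with an estimated correlation (adjusted p = 0.726), with the offset (0.17) and without lipid-laden replicate 1 (0.16). The hexokinase *Hk3* was higher (3.42 ± 0.39) and the lactate exporter *Slc16a3* lower (-3.51 ± 0.41), and of 17 glycolysis genes 3 were higher and 6 lower (3 and 7 when adjusted over the list alone; camera adjusted p = 0.239). The proliferation marker *Mki67* was at 186 and 90.6 CPM in lipid-laden against 21.7 and 9.94 CPM in lipid-free libraries (3.13 ± 0.50, and 1.72 ± 0.30 with the offset).

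Some markers of other spleen cells moved with the same comparison. The red pulp macrophage list had 3 of 16 members higher and 7 lower (3 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.00518, and adjusted p = 0.665 with an estimated correlation), with *Adgre1* (-4.97 ± 0.39) and the complement gene *C1qa* (-5.33 ± 0.82) lower. The neutrophil list had 5 of 8 members lower (0 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.0193, and 0.205 without lipid-free replicate 1). With an estimated correlation its adjusted p was 0.665. Of 13 plasmacytoid dendritic cell markers, 6 were higher and 1 lower (6 higher and 2 lower when adjusted over the list alone), including *Siglech* (5.16 ± 0.67) and *Ccr9* (4.22 ± 0.47), and the list did not pass (camera adjusted p = 0.439). The B cell receptor component *Cd79a* was at 0.544 and 29.9 CPM in lipid-laden and 41.6 and 105 CPM in lipid-free libraries (edgeR adjusted p = 0.105), and passed without lipid-laden replicate 2 (adjusted p = 0.000737) and in limma-voom (0.0114). *Cd22*, a B cell receptor of the sialic acid-binding family, was lower (-3.51 ± 0.33) and the B cell gene *Fcrla* higher (2.65 ± 0.48, edgeR adjusted p = 0.00255). The B cell list had 2 of 13 members higher and 3 lower under both adjustments and did not pass (camera adjusted p = 0.0669), while with the offset it did (0.0431; adjusted p = 0.781 with an estimated correlation and the offset). *Rpph1*, the RNA component of ribonuclease P, was at 2.24 and 3.34 CPM against 413 and 287 CPM (-6.97 ± 0.52, edgeR adjusted p = 3.09e-05).

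In total 3098 genes were higher and 2081 lower in lipid-laden than in lipid-free libraries (edgeR, Benjamini-Hochberg). Fold changes across genes had a rank correlation of -0.62 with GC content. With the offset 1599 were higher and 1961 lower, which took the share of higher calls from 59.8% to 44.9%, and 1276 genes were higher and 1160 lower in both fits. Of 78 named genes with counts in both groups, the offset moved 51 folds by over 1.5 times, 47 of them towards or past 0. Scaled by library size alone, 3932 were higher and 779 lower, with a median log2 fold change over all tested genes of 0.73 against 0.12. Without lipid-laden replicate 1 the total fell from 5179 to 2310, and without lipid-free replicate 2 it was 3222. On simulated counts for this comparison, with no change in GC content, 11% of 2-fold and 79% of 4-fold changes were recovered.

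**Figure D3:**
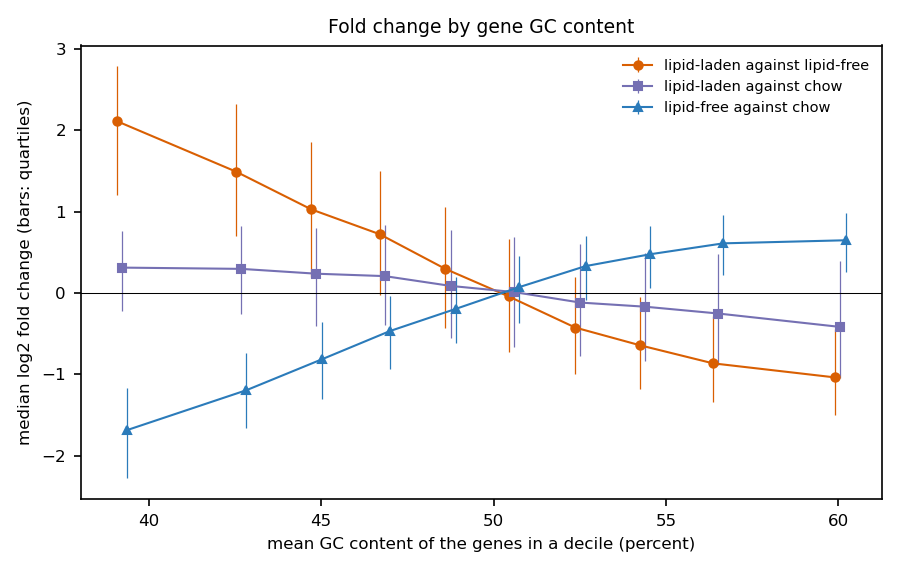
Median log2 fold change of tested genes in 10 groups of equal size by GC content, against the mean GC content of each group in percent, for the 3 comparisons; bars are quartiles and points are shifted sideways for legibility. The median runs from 2.11 to -1.04 for lipid-laden against lipid-free and from -1.68 to 0.65 for lipid-free against chow.

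**Figure D4:**
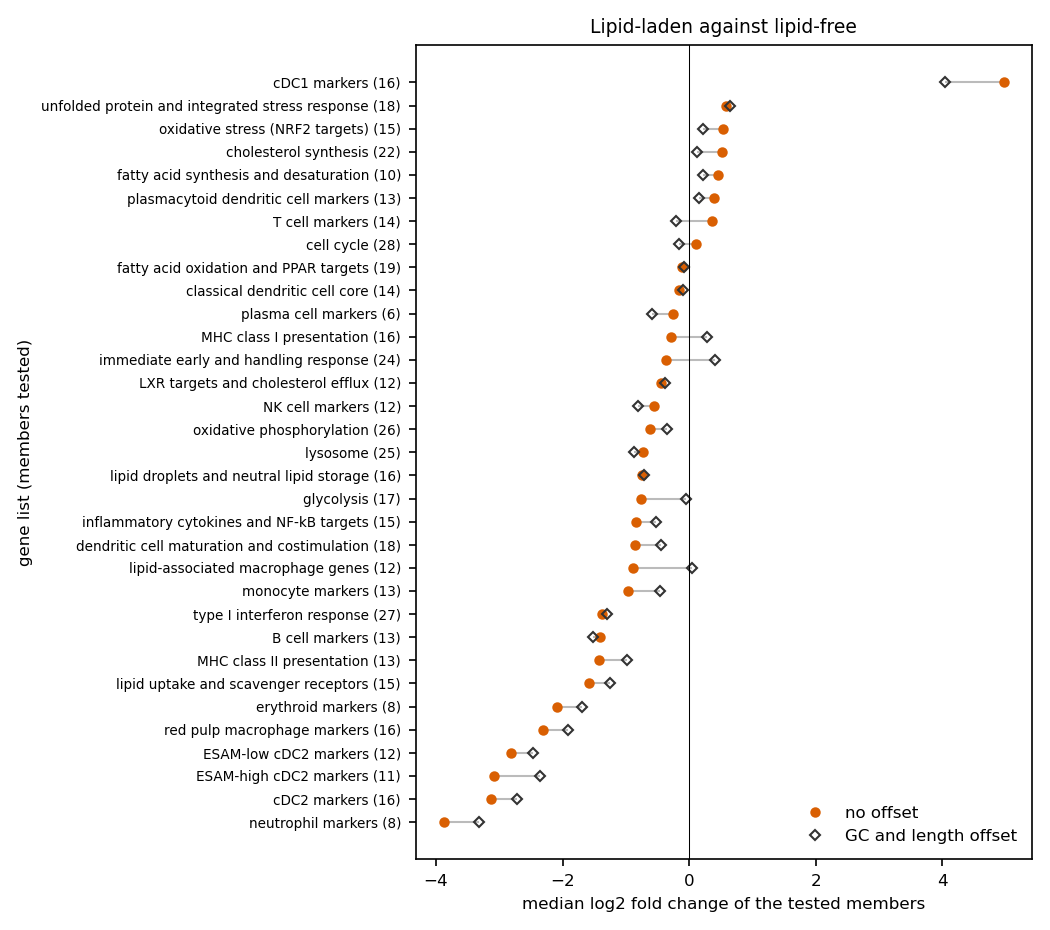
Median log2 fold change of the tested members of 33 gene lists, lipid-laden against lipid-free, without (filled circles) and with (open diamonds) the offset for GC content and length. The cDC1 list lies at 4.98 and 4.04 and the cDC2 list at -3.13 and -2.72.

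Lipid-laden cells were next compared with cells of chow-fed mice, which joins diet, lipid load and the difference in subset markers. The subset markers differed as they did against lipid-free cells. Of 16 cDC1 markers 15 were higher under both adjustments, with a median log2 fold change of 4.83. *Xcr1* changed by 6.36 ± 0.41, *Cadm1* by 5.18 ± 0.34, the lysosomal amidase *Naaa* by 4.84 ± 0.39 and the coreceptor *Cd8a*, carried by splenic cDC1, by 7.86 ± 0.66, from 4.47 and 2.27 to 658 and 944 CPM. The Wnt receptor *Fzd1* (8.31 ± 0.72) and the secreted protein *Dkk3* (7.91 ± 0.57) were among the genes with the highest fold changes. Of 16 cDC2 markers 12 were lower and 2 higher (2 higher and 14 lower when adjusted over the list alone), with *Sirpa* at -3.28 ± 0.37, *Esam* at -2.63 ± 0.32, *Clec4a4* at -4.88 ± 0.39 and *Dtx1* at -4.53 ± 0.36. The ESAM-high list had 7 of 11 lower and 1 higher (2 higher and 8 lower when adjusted over the list alone) and the ESAM-low list 8 of 12 lower and 1 higher under both adjustments. *Tgm2* (-6.17 ± 0.40), *Cd101* (-6.19 ± 0.43) and the sodium-calcium exchanger *Slc8a2* (-6.19 ± 0.41) were among the lowest. The edgeR adjusted p of the genes named here was at most 0.00049. The cDC1, cDC2, ESAM-high and ESAM-low lists passed (camera adjusted p = 4.46e-43, 1.31e-12, 1.18e-09 and 1.45e-05). With an estimated correlation the adjusted p was 0.0434, 0.0742, 0.0742 and 0.479, and with the offset as well it was 0.14 for the cDC1 list. At the preset correlation the cDC1 list passed with the offset too (camera adjusted p = 1.98e-47). Without the offset the estimated correlations were 0.043, 0.029, -0.037 and 0.215, and that of the ESAM-high list again lay below the preset one.

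Against chow, *Plin2* (2.62 ± 0.43) and *Cd36* (5.02 ± 0.56) were again higher and *Fabp5* (-3.37 ± 0.41) lower. The stearoyl-CoA desaturase *Scd1* (3.82 ± 0.62), the desaturase *Fads1* (1.88 ± 0.39) and *Acadl* (1.22 ± 0.30) were higher, with edgeR adjusted p of 0.00251, 0.00935 and 0.0233. The fatty acid synthase *Fasn* (1.10 ± 0.29) and *Cpt1a* (1.14 ± 0.32) were higher, at edgeR adjusted p of 0.0301 and 0.0377. *Ldlr* (-1.15 ± 0.37), *Abcg1* (0.89 ± 0.35), *Abca1* (1.30 ± 0.76), *Srebf1* (-0.15 ± 0.31), *Hmgcr* (0.88 ± 0.44), *Hmgcs1* (0.15 ± 0.53), *Sqle* (-0.22 ± 0.50) and *Lpl* (-1.83 ± 1.01) did not pass, with edgeR adjusted p from 0.0583 for *Ldlr* to 0.869 for *Hmgcs1*. The call of *Fasn* was lost without chow replicate 1 (adjusted p = 0.0615), without lipid-free replicate 1 (0.0516), without lipid-free replicate 2 (0.0526), without lipid-laden replicate 1 (0.0932), without lipid-laden replicate 2 (0.0548), with the offset (0.131) and in a fit of only the 4 libraries compared (0.0625). The call of *Cpt1a* was lost without chow replicate 1 (adjusted p = 0.0691), without chow replicate 2 (0.055), without lipid-laden replicate 1 (0.0788), without lipid-laden replicate 2 (0.13) and in a fit of only the 4 libraries compared (0.0578). *Ldlr* passed with no filter on low counts (adjusted p = 0.0342), without chow replicate 2 (0.0162), with the offset (0.0134), in DESeq2 (0.0173) and in limma-voom (0.0496). *Abcg1* passed when scaled by library size alone (adjusted p = 0.0276), with no filter on low counts (0.0451) and without chow replicate 2 (0.0272). *Hmgcr* passed without chow replicate 1 (adjusted p = 0.0064). *Acadl* lost its call without chow replicate 2 (adjusted p = 0.0677). *Fads1* and *Acadl* lost their calls without lipid-laden replicate 1 (adjusted p = 0.0699 and 0.0573). *Acadl* lost its call without lipid-laden replicate 2 (adjusted p = 0.0963). In this comparison, of 16 lipid droplet genes 2 were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 0.862), of 15 lipid uptake genes 1 was higher and 4 lower (2 and 6 when adjusted over the list alone; camera adjusted p = 0.115) and of 12 LXR targets 1 was higher and 3 lower (3 and 4 when adjusted over the list alone; camera adjusted p = 0.237). Further, of 10 fatty acid synthesis genes 2 were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 0.186), of 19 fatty acid oxidation genes 2 were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 0.688) and of 22 cholesterol synthesis genes 0 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.513). None of the 6 lipid lists passed the set test, with camera adjusted p from 0.115 to 0.862.

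*Cd86* (2.19 ± 0.34), *Il12b* (2.90 ± 0.51), *Cxcl9* (3.06 ± 0.41) and the chemokine gene *Ccl22* (1.74 ± 0.36) were higher than in chow libraries, and *Il1b* (-2.27 ± 0.31) and *Relb* (-2.13 ± 0.41) were lower. *Cd40* was lower (-1.04 ± 0.31, edgeR adjusted p = 0.0438), and *Irf4* (-0.97 ± 0.33), *Zbtb46* (0.54 ± 0.38), *H2-Ab1* (-1.04 ± 0.60), *Cd80* (0.24 ± 0.39), *Ccr7* (-0.47 ± 0.40) and *Tnf* (-0.43 ± 0.45) did not pass (adjusted p = 0.0703, 0.358, 0.26, 0.706, 0.45 and 0.539). Of 27 type I interferon response genes 15 were lower and 2 higher (2 higher and 16 lower when adjusted over the list alone), with *Rtp4* at -4.47 ± 0.40, *Oas1a* at -4.93 ± 0.54 and *Ifit3* at -3.84 ± 0.48. The list passed (camera adjusted p = 2.29e-09; adjusted p = 0.423 with an estimated correlation). Of 13 MHC class II presentation genes 4 were lower (0 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.00239; adjusted p = 0.755 with an estimated correlation and 0.0849 with the offset). Of 26 oxidative phosphorylation genes 6 were lower (0 higher and 12 lower when adjusted over the list alone; camera adjusted p = 0.000676; adjusted p = 0.755 with an estimated correlation and 0.172 with the offset). The glycolytic enzymes *Hk3* (5.28 ± 0.43) and *Pfkp* (2.20 ± 0.31) were higher, as were *Hsp90b1* (1.65 ± 0.40) and *Hspa5* (1.29 ± 0.34), but of 17 glycolysis genes 3 were higher and 1 lower (5 and 1 when adjusted over the list alone; camera adjusted p = 0.404), with a median of -0.22. The stress response list had 4 of 18 members higher and 1 lower under both adjustments and passed with the offset (camera adjusted p = 0.0187), not without it (0.221), nor with the offset and an estimated correlation (adjusted p = 0.308). Exons of *Hk3* and *Pfkp* overlap other genes on the opposite strand. The metalloelastase *Mmp12* (-4.94 ± 0.50), the monocyte-associated gene *S100a4* (-4.30 ± 0.50) and the macrophage marker *Adgre1* (-5.31 ± 0.39) were lower, but of 16 red pulp macrophage markers 3 were higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.221) and of 13 monocyte markers 2 were higher and 4 lower (3 and 4 when adjusted over the list alone; camera adjusted p = 0.226). Among activation genes, of 18 maturation genes 2 were higher and 4 lower (2 and 5 when adjusted over the list alone; camera adjusted p = 0.231) and of 15 inflammatory genes 2 were higher and 4 lower (2 and 5 when adjusted over the list alone; camera adjusted p = 0.404). The call of *Cd40* was lost when scaled by library size alone (adjusted p = 0.158), with no filter on low counts (0.0634), without chow replicate 2 (0.216), without lipid-free replicate 1 (0.0738), without lipid-free replicate 2 (0.0756), without lipid-laden replicate 1 (0.222), without lipid-laden replicate 2 (0.0737) and in a fit of only the 4 libraries compared (0.0804). The call of *Hspa5* was lost without chow replicate 2 (adjusted p = 0.184), without lipid-free replicate 1 (0.0528), without lipid-free replicate 2 (0.0542), without lipid-laden replicate 1 (0.0559) and in a fit of only the 4 libraries compared (0.0704). *Zbtb46* passed without chow replicate 1 (adjusted p = 0.0428). *Hsp90b1* lost its call without chow replicate 2 (adjusted p = 0.0946). *Ccl22* lost its call without lipid-laden replicate 1 (adjusted p = 0.0589). *Irf4* passed with the offset (adjusted p = 0.00628), and *Ccr7* and *Tnf* turned to log2 fold changes of 0.06 and 0.19. *H2-Ab1* and *Irf4* passed in DESeq2 (adjusted p = 0.0433 and 0.0323).

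Against chow, the T cell list had 3 of 14 members higher and 1 lower (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0212; adjusted p = 0.696 with an estimated correlation). Its call was lost without chow replicate 1 (0.0902) and without lipid-laden replicate 2 (0.158). The erythroid list had 2 of 8 members lower (0 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.0129; adjusted p = 0.755 with an estimated correlation), and its call was lost without chow replicate 1 (0.101) and with the offset (0.0857). The heme synthesis gene *Alas2* (-2.91 ± 0.62) and *C1qa* (-3.35 ± 0.79) were lower, *Siglech* was higher (3.56 ± 0.59), and *Cd79a* did not pass (2.52 ± 1.15, edgeR adjusted p = 0.159). In their lists, of 13 plasmacytoid dendritic cell markers 2 were higher and 2 lower (6 and 2 when adjusted over the list alone; camera adjusted p = 0.119) and of 13 B cell markers 1 was higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.834). The call of *C1qa* was lost when scaled by library size alone (adjusted p = 0.0666), without chow replicate 2 (0.0988), without lipid-laden replicate 1 (0.122) and in limma-voom (0.0555). *Alas2* lost its call when scaled by library size alone (adjusted p = 0.0866). *Cd79a* passed without lipid-laden replicate 1 (adjusted p = 0.00225). *Alas2* lost its call without lipid-laden replicate 2 (adjusted p = 0.0514).

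Altogether 824 genes were higher and 906 lower in lipid-laden than in chow libraries (edgeR, Benjamini-Hochberg), and 1035 and 1279 with the offset, which moved the folds of 7 of 56 named genes by over 1.5 times, all 7 towards or past 0. Scaled by library size alone, 814 were higher and 388 lower, with a median over all tested genes of 0.46 against 0.04. The total of 1730 became 3153 without chow replicate 1, 938 without chow replicate 2 and 618 without lipid-laden replicate 1. Both comparisons of lipid-laden libraries called 629 genes higher and 739 lower, against 211 and 156 for independent lists of these lengths, and no gene was called in opposite directions. In 20 simulations of unchanged groups neither comparison made more than 2 calls and 0 were shared, a value that says little of lists with many calls. At an unadjusted p under 0.05 the simulations shared 36.6 genes higher and 67.0 lower on average, against 1321 and 1462 in these data. Part of the excess may come from the lipid-laden libraries that both comparisons share.

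Lipid-free cells of the western-type diet were last compared with chow cells. The labels do not split chow cells by lipid content, so this contrast joins diet with the choice of lipid-free cells. Of 16 cDC1 markers 1 was higher and 2 were lower (2 higher and 2 lower when adjusted over the list alone), and of 16 cDC2 markers 1 was lower under both adjustments. *Xcr1* (-0.78 ± 0.37), *Sirpa* (0.87 ± 0.34), *Esam* (0.46 ± 0.30), *Zbtb46* (-0.03 ± 0.38) and *Irf4* (0.24 ± 0.32) did not pass (edgeR adjusted p = 0.169, 0.104, 0.315, 0.965 and 0.634). The cDC1 and cDC2 lists had medians of -0.23 and 0.20 and did not pass (camera adjusted p = 0.94 and 0.756), and with the offset the medians were 0.45 and 0.24. Of 11 ESAM-high markers 1 was higher and 1 lower (6 higher and 1 lower when adjusted over the list alone). Their median was 0.92, and 0.21 with the offset (camera adjusted p = 0.0521 and 0.239). Of 12 ESAM-low markers 0 were higher and 2 lower (1 and 2 when adjusted over the list alone, median 0.09, camera adjusted p = 0.940). *Xcr1* turned with the offset to a log2 fold change of 0.51. *Sirpa* passed in DESeq2 (adjusted p = 0.024). The *Zbtb46* value was close to 0 and took either sign, from -0.45 without chow replicate 2 to 0.64 without chow replicate 1.

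Of the lipid genes fixed beforehand, *Sqle* was lower (-2.23 ± 0.54, edgeR adjusted p = 0.0401). Its log2 fold change was -2.07 with the offset, -2.50 scaled by library size alone and -1.15 without chow replicate 1. *Plin2* (0.92 ± 0.41), *Cd36* (-1.65 ± 0.55), *Srebf1* (1.08 ± 0.31), *Hmgcs1* (-1.95 ± 0.56), *Cpt1a* (0.91 ± 0.32), *Abcg1* (0.70 ± 0.35), *Hmgcr* (-0.80 ± 0.45), *Abca1* (0.97 ± 0.77), *Fabp5* (-0.37 ± 0.37), *Ldlr* (0.13 ± 0.36) and *Lpl* (0.06 ± 0.94) did not pass, with edgeR adjusted p from 0.0512 for *Srebf1* to 0.971 for *Lpl*. The call of *Sqle* was lost when scaled by library size alone (adjusted p = 0.112), without chow replicate 1 (0.24), without lipid-free replicate 2 (0.0639), without lipid-laden replicate 2 (0.0562), with the offset (0.0707), in limma-voom (0.0581) and in a fit of only the 4 libraries compared (0.05). *Cd36* passed with no filter on low counts (adjusted p = 0.0028), without chow replicate 2 (0.0358), without lipid-free replicate 1 (0.00251) and in DESeq2 (0.0152). *Srebf1* passed with RLE size factors (adjusted p = 0.0475), with no filter on low counts (0.0214), with a stricter filter on low counts (0.0494), without chow replicate 2 (0.0269), without lipid-laden replicate 1 (0.0409), in DESeq2 (0.0109), in limma-voom (0.0451) and in a fit of only the 4 libraries compared (0.045). *Hmgcs1* passed with no filter on low counts (adjusted p = 0.000216), with a stricter filter on low counts (0.0498), without the robust prior (0.0495), without chow replicate 2 (0.00527), without lipid-free replicate 1 (0.00406) and in DESeq2 (0.0071). *Plin2*, *Abcg1* and *Hmgcr* passed without chow replicate 2 (adjusted p = 0.0151, 0.0329 and 0.0303). *Ldlr* turned with the offset to a log2 fold change of -0.49. *Cpt1a* passed in DESeq2 (adjusted p = 0.0354). None of the 6 lipid lists passed without the offset, with camera adjusted p from 0.0521 for LXR targets and 0.0700 for lipid droplets to 0.940 for lipid uptake. Of 22 cholesterol synthesis genes 2 were lower (0 higher and 4 lower when adjusted over the list alone), of 12 LXR targets 1 was higher (2 higher and 0 lower when adjusted over the list alone), and of 16 lipid droplet genes none was called. Of 19 fatty acid oxidation genes and of 15 lipid uptake genes 1 each was higher under both adjustments, and of 10 fatty acid synthesis genes 1 was lower (1 higher and 1 lower when adjusted over the list alone). With the offset the cholesterol synthesis (median -0.34), lipid droplet (0.46) and fatty acid oxidation (0.30) lists passed (camera adjusted p = 0.0372 for each), with no member called. With the offset and an estimated correlation adjusted p was 0.833 for each.

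Of the activation genes fixed beforehand, *Il12b* was lower (-2.16 ± 0.59, edgeR adjusted p = 0.0468). *Cd86* (-1.06 ± 0.33), *Il1b* (-0.73 ± 0.29), *Cd80* (-0.62 ± 0.39), *Tnf* (0.40 ± 0.45), *H2-Ab1* (0.33 ± 0.60), *Cd40* (0.17 ± 0.30), *Ccr7* (-0.10 ± 0.40) and the plasmacytoid dendritic cell marker *Siglech* (-1.61 ± 0.71) did not pass, with edgeR adjusted p from 0.0625 for *Cd86* to 0.879 for *Ccr7*. As lists, of 18 maturation genes 1 was higher and 0 lower (0 and 0 when adjusted over the list alone; camera adjusted p = 0.578), of 15 inflammatory genes 0 were higher and 1 lower (0 and 0 when adjusted over the list alone; camera adjusted p = 0.940) and of 13 plasmacytoid dendritic cell markers 1 was higher and 0 lower (2 and 3 when adjusted over the list alone; camera adjusted p = 0.901). The call of *Il12b* was lost when scaled by library size alone (adjusted p = 0.112), without chow replicate 1 (0.0741), without chow replicate 2 (0.052), without lipid-free replicate 2 (0.237), without lipid-laden replicate 1 (0.0666), without lipid-laden replicate 2 (0.0694), with the offset (0.174), in limma-voom (0.11) and in a fit of only the 4 libraries compared (0.114). *Cd86* passed with no filter on low counts (adjusted p = 0.0453), without chow replicate 2 (0.0429) and in DESeq2 (0.0309). *Cd80*, *Cd86* and *Il1b* turned with the offset to log2 fold changes of 0.61, 0.05 and 0.16.

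*Rpph1*, the RNA component of ribonuclease P (chromosome 14, 50807449 to 50807767, overlapping an exon of *Ccnb1ip1*), was at 413 and 287 CPM in lipid-free against 10.5 and 22.7 CPM in chow and 2.24 and 3.34 CPM in lipid-laden libraries (log2 fold change against chow 4.41 ± 0.45, edgeR adjusted p = 0.0125). It passed with the offset too (4.26 ± 0.26, adjusted p = 7.61e-05). The small nucleolar RNA *Snord17* (4.96 ± 0.81) was higher, and *Met* was without counts in lipid-free libraries and at 1.92 and 2.38 CPM in chow, at least 6.82-fold lower. *Scd1* (2.85 ± 0.61), the heat shock genes *Hspa1a* (2.57 ± 0.49) and *Hspa1b* (2.30 ± 0.49), whose near-identical sequences may share reads, the receptor *Axl* (2.65 ± 0.54) and *Hk3* (1.85 ± 0.40) were higher, and *Idi1* (-3.13 ± 0.66), *Mki67* (-2.14 ± 0.48), the thymidylate synthase *Tyms* (-1.68 ± 0.37) and *Clec4a4* (-1.57 ± 0.34) were lower, with edgeR adjusted p from 0.0352 to 0.0369. The call of *Hk3* was lost without chow replicate 1 (adjusted p = 0.0765), without lipid-laden replicate 2 (0.0503), with the offset (0.0803) and in a fit of only the 4 libraries compared (0.0509). *Axl*, *Hspa1a*, *Hspa1b*, *Scd1*, *Idi1*, *Mki67* and *Clec4a4* lost their calls without chow replicate 1 (adjusted p = 0.058, 0.0516, 0.058, 0.066, 0.107, 0.0819 and 0.0705). *Mki67*, *Clec4a4* and *Tyms* lost their calls without lipid-free replicate 2 (adjusted p = 0.12, 0.172 and 0.118). *Tyms* lost its call without lipid-laden replicate 2 (adjusted p = 0.0501). *Axl*, *Snord17*, *Hspa1a*, *Hspa1b*, *Scd1*, *Idi1*, *Mki67*, *Met* and *Tyms* lost their calls with the offset (adjusted p = 0.0651, 0.0552, 0.0552, 0.0648, 0.0552, 0.108, 0.0552, 0.0552 and 0.105), and *Clec4a4* turned to a log2 fold change of 0.12. In the fit with the offset the log2 fold changes were 4.96 for *Snord17*, 3.20 for *Scd1*, 2.15 for *Axl*, 1.87 for *Hspa1a*, 1.66 for *Hspa1b*, 1.19 for *Hk3*, -1.28 for *Tyms*, -1.60 for *Mki67* and -1.74 for *Idi1*.

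Of 13 B cell markers 4 were higher in lipid-free than in chow libraries (6 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.00166; adjusted p = 0.973 with an estimated correlation). *Cd79a* was at 41.6 and 105 CPM against 2.48 and 2.83 CPM (4.78 ± 1.23, edgeR adjusted p = 0.0421). *Cd19* changed by 4.43 ± 1.01 and the Fc receptor *Fcer2a* by 2.99 ± 0.83. *Fcmr*, which is not a member of the list, changed by 5.29 ± 1.32. The T cell list had 1 of 14 members higher, *Cd3e* (2.76 ± 0.58), under both adjustments (camera adjusted p = 0.0217; adjusted p = 0.973 with an estimated correlation). The red pulp macrophage list had 1 of 16 members higher and 1 lower (7 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.00837; adjusted p = 0.973 with an estimated correlation). Of 12 NK cell markers 2 were lower and none higher under both adjustments (camera adjusted p = 0.578), and none was called with the offset. *C1qa* was at 36.3 and 17 against 3.05 and 10.7 CPM (1.98 ± 0.68, edgeR adjusted p = 0.0762). The glycolysis list passed (camera adjusted p = 0.00166) with 1 of 17 members called under both adjustments, and did not with the offset (0.0651) or with an estimated correlation (adjusted p = 0.973). Of 28 cell cycle genes 6 were lower (0 higher and 10 lower when adjusted over the list alone, camera adjusted p = 0.0600). With the offset the B cell, red pulp macrophage and T cell lists passed again, with no member called (camera adjusted p = 4.63e-06, 9.53e-06 and 9.51e-05). The cell cycle, lysosome and MHC class II lists also passed with it, with no member called (camera adjusted p = 0.0383, 0.013 and 0.0131). With the offset and an estimated correlation, camera adjusted p was 0.833 for each of these lists. Without the offset 2 of 25 lysosome genes were higher and 1 lower under both adjustments. None of 13 MHC class II genes was called without it (camera adjusted p = 0.0521 for each of these 2 lists). The call of *Cd79a* was lost with no filter on low counts (adjusted p = 0.381), without chow replicate 1 (0.548), without chow replicate 2 (0.389), without lipid-free replicate 1 (0.347), without lipid-free replicate 2 (0.529), with the offset (0.083) and in limma-voom (0.0507). The call of *Cd19* was lost without chow replicate 1 (adjusted p = 0.292), without chow replicate 2 (0.0587), without lipid-free replicate 2 (0.0741) and with the offset (0.0778). The call of *Fcer2a* was lost without chow replicate 1 (adjusted p = 0.172), without chow replicate 2 (0.0585), without lipid-free replicate 2 (0.144), with the offset (0.0949) and in limma-voom (0.0665). The call of *Fcmr* was lost with no filter on low counts (adjusted p = 0.363), without chow replicate 1 (0.539), without chow replicate 2 (0.339), without lipid-free replicate 1 (0.332), without lipid-free replicate 2 (0.504) and with the offset (0.0748). *C1qa* passed with no filter on low counts (adjusted p = 0.000986), without chow replicate 2 (0.0162), without lipid-free replicate 2 (0.0393), in DESeq2 (0.0175) and in limma-voom (0.0431). *Cd3e* lost its call without chow replicate 1 (adjusted p = 0.0677). *Cd3e* lost its call with the offset (adjusted p = 0.0552). The log2 fold changes with the offset were 5.13 for *Fcmr*, 4.50 for *Cd79a*, 3.97 for *Cd19*, 3.72 for *Cd3e* and 2.83 for *Fcer2a*.

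In total 328 genes were higher and 899 lower in lipid-free than in chow libraries (edgeR, Benjamini-Hochberg). Fold changes across genes had a rank correlation of 0.72 with GC content. With the offset 2 genes were called, *Rpph1* and *Sec23b* (log2 fold change 2.15 ± 0.27, adjusted p = 0.0466, against 0.71 without the offset), named because they were called and chosen after their values were seen, and 2327 genes had an unadjusted p under 0.05. The offset moved 17 of 43 named folds by over 1.5 times, 15 of them towards or past 0. Scaled by library size alone no gene was called by edgeR (3441 at an unadjusted p under 0.05), which ended every call named here, against 1050 calls by limma-voom and 2493 by DESeq2 with their own scaling. Folds stayed close to those given above, with log2 fold changes of 4.32 for *Rpph1*, 4.59 for *Cd79a*, 2.75 for *Scd1*, -2.35 for *Mki67* and -3.41 for *Idi1*. The median over all tested genes was -0.29 with that scaling and -0.13 with TMM. The total of 1227 became 163 without chow replicate 1, 2359 without chow replicate 2, 206 without lipid-free replicate 2 and 330 without lipid-laden replicate 2. On simulated counts for this comparison 2% of 2-fold and 76% of 4-fold changes were recovered.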

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

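The second marker lists, the histone genes and the removal of the genes with the most counts were set before their results were seen; the tests of the GC trend, swapped or exchanged labels, diet alone and a change within cDC2 cells, and the offset itself, were chosen after.

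Lipid-laden and lipid-free libraries, both of the western-type diet, differed for 11 gene lists by camera, and some of these lists share members. The labels do not split chow cells by lipid content, so no effect of diet within lipid-laden or lipid-free cells was measured. The median log2 fold change of that difference was 4.98 for cDC1 markers, -3.13 for cDC2 markers, -3.09 for ESAM-high and -2.81 for ESAM-low cDC2 markers. Against chow these lists had medians of 4.83, -2.72, -2.63 and -2.58 in lipid-laden and -0.23, 0.20, 0.92 and 0.09 in lipid-free cells. For neutrophil markers the difference was -3.88 (-1.30 and 2.39 against chow) and for red pulp macrophage markers -2.30 (-0.60 and 1.58). For MHC class II presentation it was -1.43 (-1.12 and 0.46), and for the type I interferon response -1.37 (-1.51 and -0.32, the last 0.15 with the offset). For the lysosome it was -0.72 (-0.24 and 0.20), for oxidative phosphorylation -0.63 (-0.91 and -0.16, the last 0.083 with the offset, which also ended the call of the difference at camera adjusted p = 0.170), and for LXR targets -0.45 (-0.37 and 0.47). With an estimated correlation the difference held for the cDC1 list alone of these 11.

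The lipid-laden libraries had cDC1 markers at high and cDC2 markers at low levels, although the series title names cDC2s. A trend with GC content and length leaves the cDC1 median at 4.04 with the offset. A swap of single libraries lacks a partner because every other library lay at least 4.28 log2 units below on the mean cDC1 level. For diet alone, the nearest contrast, lipid-free against chow, gave -0.23 (0.45 with the offset), though chow cells were not split by lipid content. A candidate explanation is that cDC1 cells made up most of the lipid-laden cells: 84.6% of a second cDC1 list was higher (11 of 13, 1 lower) and 9 of 13 members of a second cDC2 list were lower and 1 higher. The abundant cDC1 genes *Naaa* and *Irf8* were higher, with *Naaa* at 1449 and 1832 CPM against 42.5 and 54.7 CPM and *Irf8* at 1829.8 and 2299 against 171 and 158 CPM in lipid-free libraries, but no library of pure cDC1 cells was used to set the level this needs, and the sources used here do not say which sort or gate would have removed such cells. A change within cDC2 cells under lipid load (cDC2 median -3.13) cannot be told apart from this in bulk libraries. Neither can an exchange of all libraries between the lipid-laden and lipid-free groups, which leaves no library out of place. The lipid droplet list did not pass (median -0.74, camera adjusted p = 0.358). *Plin2* (1.70 ± 0.41) and *Cd36* (6.68 ± 0.62) were higher in the libraries labelled lipid-laden. These 2 genes cannot decide on an exchange, as cells of another subset could differ in them whatever their lipid load.

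Fold changes in lipid-free against chow followed gene GC content, with a rank correlation across genes of 0.72. A few genes taking most of the counts stay untested, since leaving out the 10 genes with the most counts shifts all fold changes alike and so could not move the correlation (0.722). The GC trend may account for much of the count of calls, as 2 genes were called with the offset against 1227 without it (1 in both), with folds of some genes moved (*Idi1* from -3.13 ± 0.66 to -1.74 ± 0.49) and of others kept. *Scd1* went from 2.85 ± 0.61 to 3.20 ± 0.62 and lost its call (edgeR adjusted p from 0.0363 to 0.0552, range over alternatives 1.56e-05 to 0.112) although its unadjusted p went from 0.000689 to 0.000353, because fewer genes had small p-values and its rank went from 222 to 75 among 12107 genes. For carry-over of RNA without a poly(A) tail, the outcome set beforehand against it was a histone median under 0 with the offset. The median of 22 histone genes was -0.00903 (quartiles -0.53 and 0.33), which met that outcome by far less than the spread. The rule applied asked instead for an upper quartile under 0, which was not met. Fewer dividing cells would lower these genes too, so carry-over cannot be told apart, and an effect of diet stays open as untested. None of the histone genes was called. Other non-coding RNAs, chosen with their values in view, were higher in lipid-free than in chow libraries. With the offset *Rpph1* changed by 4.26 and *Snord17* by 4.96. *Rmrp* had 908 and 930 against 290 and 329 counts. *Rn45s* took 10.7% and 15.3% against 6.41% and 9.19% of counts.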

How the results depend on the processing

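The offset for GC content and length, alone and with libraries left out, was chosen after the data were examined; the other alternatives were set before. Of the gene results under alternatives, over 180 pairs of gene and comparison, 2601 kept direction and side of the threshold, 161 lost a call, 67 gained one and 46 changed sign. Of 24 list calls, fry kept 8 and the offset kept 19. Camera with an estimated correlation kept 2, the cDC1 calls in both comparisons of lipid-laden libraries. The ESAM-high list lost its call in both at an estimated correlation of -0.037, below the preset one. A call lost this way therefore does not by itself show correlation among the genes of a list. With 1 library left out a list call ended in 5 cases. In lipid-laden against lipid-free, RLE size factors, library size alone, both other filters, the robust prior, DESeq2, limma-voom, the offset and a fit of 4 libraries gave 3560 to 5732 genes against 5179, and in lipid-laden against chow 1202 to 2546 against 1730. Leaving out libraries gave 2310 to 5955 in lipid-laden against lipid-free, 618 to 3153 in lipid-laden against chow and 163 to 2359 in lipid-free against chow (1227 with all libraries). In lipid-free against chow, edgeR called 0 genes scaled by library size alone (3441 at an unadjusted p under 0.05; 2493 by DESeq2 and 1050 by limma-voom), 2351 with no filter on low counts and 2 with the offset. With the offset and 1 library left out, lipid-laden against lipid-free fell to 2779 without lipid-free replicate 1, 2181 without lipid-free replicate 2, 1647 without lipid-laden replicate 1 and 2916 without lipid-laden replicate 2, and lipid-laden against chow, at 2314, fell to 1307 without chow replicate 2 and 1116 without lipid-laden replicate 1. Lipid-free against chow gave 14 and 128 without chow replicates 1 and 2, 221 and 5 without lipid-free replicates 1 and 2, and 198 and 197 without lipid-laden replicates 1 and 2. With library size alone as the scaling, the log2 fold change of *Ccr7* was 0.29 in lipid-laden against lipid-free, the log2 fold changes of *Srebf1*, *Sqle*, *Ccr7* and *Tnf* were 0.32, 0.13, 0.086 and 0.089 in lipid-laden against chow and the log2 fold changes of *Ldlr* and *Lpl* were -0.10 and -0.12 in lipid-free against chow. Under the offset for GC content and length, the log2 fold changes of *Abca1*, *Cd80* and *Ccr7* were -0.73, -0.48 and 0.36 in lipid-laden against lipid-free, the log2 fold changes of *Ccr7* and *Tnf* were 0.057 and 0.19 in lipid-laden against chow and the log2 fold changes of *Ldlr*, *Xcr1*, *Clec4a4*, *Cd80*, *Cd86* and *Il1b* were -0.49, 0.51, 0.12, 0.61, 0.051 and 0.16 in lipid-free against chow. *Zbtb46* in lipid-free against chow, at -0.03, was 0.034 with RLE size factors, 0.034 in DESeq2, 0.037 in limma-voom, 0.016 in a fit of only the 4 libraries compared and 0.053 with the replicate block. With 1 library left out at a time, genes that took both signs ranged from -0.33 to 1.69 for *Abca1* and -0.97 to 0.031 for *Ccr7* in lipid-laden against lipid-free, and from -0.35 to 0.14 for *Srebf1*, -0.44 to 1.20 for *Hmgcs1*, -0.80 to 0.80 for *Sqle*, -0.16 to 0.83 for *Cd80*, -1.01 to 0.13 for *Ccr7* and -2.26 to 3.48 for *Cd79a* in lipid-laden against chow. Those ranges were -0.26 to 0.73 for *Ldlr*, -0.37 to 2.20 for *Abca1*, -1.34 to 0.12 for *Hmgcr*, -0.12 to 0.22 for *Lpl*, -0.66 to 0.13 for *Fabp5*, -1.03 to 0.025 for *Cd80*, -0.44 to 0.49 for *Ccr7*, -0.073 to 0.76 for *Tnf* and -0.45 to 0.64 for *Zbtb46* in lipid-free against chow. For these differences the cause was not tested. A library left alone in its group was taken to vary like the other groups. At these depths 11%, 8% and 2% of simulated 2-fold changes were recovered. The order is lipid-laden against lipid-free, lipid-laden against chow and lipid-free against chow. The simulation changed far fewer genes than were called in these data, and adjusted p-values depend on how many genes change. These shares therefore do not give the share of 2-fold changes detectable here. In lipid-laden against lipid-free, the genes highest in GC content had a median log2 fold change of -1.04. Of these 1166 genes, 536 were called lower and 38 higher.

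The samples shared only a replicate number, since there were fewer than 3 pairs per comparison and nothing in the labels links the numbers, and the main test was not paired. Deviations from the group means had correlations across genes of 0.258 for chow and lipid-free, 0.33 for chow and lipid-laden and 0.111 for lipid-free and lipid-laden samples of one number. With a replicate block the counts were 6567, 3829 and 3754 genes in the order used above, 15 gene results gained a call (*H2-Ab1* and *Cd80* in lipid-laden against lipid-free, *Ldlr*, *Abcg1*, *Hmgcr* and *Irf4* in lipid-laden against chow, and *Sirpa*, *C1qa*, *Plin2*, *Cd36*, *Srebf1*, *Hmgcs1*, *Cpt1a*, *Cd86* and *Il1b* in lipid-free against chow), *Cd79a* in lipid-free against chow lost it (edgeR adjusted p = 0.160), and 1 list call ended, that of T cell markers in lipid-laden against chow (camera adjusted p = 0.0611).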

Other observations

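The tests of histone genes used a list written before its values were seen; the choice of the other values was made after.

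Further gene lists were compared between lipid-laden and lipid-free libraries. Of 15 targets of the oxidative stress regulator NRF2, 5 were higher and 4 lower (7 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.871). Of 28 cell cycle genes, 9 were higher and 2 lower under both adjustments (0.65). Of 13 monocyte markers, 3 were higher and 5 lower under both adjustments (0.131), and of 16 MHC class I presentation genes 3 were higher and 2 lower (3 higher and 1 lower when adjusted over the list alone, 0.608). Of 24 genes of the immediate early and handling response, 3 were higher and 5 lower under both adjustments (0.405). The classical dendritic cell core list had 3 of 14 members higher and 2 lower under both adjustments (0.546), and the NK cell list 1 of 12 higher and 1 lower under both (0.65). Of 12 lipid-associated macrophage genes, 3 were higher and 5 lower under both adjustments (0.165). Of 8 erythroid markers 4 were lower and none higher under both adjustments (median log2 fold change -2.09, 0.0669), and none was called with the offset. Of 14 T cell markers 2 were higher and 2 lower under both adjustments (0.871), and of 6 plasma cell markers 1 was higher and 1 lower (1 higher and 0 lower when adjusted over the list alone, 0.608). The platelet and the endothelial and stromal lists had 4 tested members each, too few for the set test, with 1 platelet marker lower under both adjustments. With the offset the counts were 5 higher and 4 lower for NRF2 targets, 2 and 2 for the cell cycle, 1 and 4 for monocytes, 5 and 1 for MHC class I presentation, 5 and 1 for the immediate early response, 2 and 3 for the dendritic cell core, 0 and 2 for NK cells and 4 and 5 for lipid-associated macrophage genes, and none of these lists passed. The median changed sign with it for the cell cycle (0.12 to -0.16), MHC class I presentation (-0.28 to 0.29), the immediate early response (-0.36 to 0.41), T cells (0.36 to -0.21) and lipid-associated macrophage genes (-0.89 to 0.05). In lipid-free against chow the camera adjusted p was 0.901 for NRF2 targets, 0.344 for MHC class I presentation, 0.413 for the immediate early response and 0.138 for the dendritic cell core.

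Of 22 tested replication-dependent histone genes, 9 were lower in lipid-laden than in lipid-free libraries and none higher, with a median log2 fold change of -2.37 and no set test. With the offset 3 were lower and the median was -1.40. *Mki67* was higher in the same comparison (3.13 ± 0.50, edgeR adjusted p = 0.00145, and 1.72 ± 0.30 with the offset, 0.00204).

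Some values stood apart by library. *Lars2* took 1.05% and 1.79% of counts in chow, 1.77% and 3.27% in lipid-free and 0.726% and 0.344% in lipid-laden libraries. *Rmrp*, the RNA component of a mitochondrial RNA processing ribonuclease, had 290 and 329 counts in chow, 908 and 930 in lipid-free and 44 and 43 in lipid-laden libraries. The Y-linked *Ddx3y* had 799 and 125, 94 and 52, and 1612 and 626 counts in the same order. *Eif2s3y*, *Uty* and *Kdm5d*, also Y-linked, had counts in every library. *Xist*, a gene of female cells, had 2 and 4, 1 and 6, and 1 and 6 counts, so these values do not mark a difference in sex. The hemoglobin genes *Hba-a1* and *Hbb-bs* were listed at 0 counts in all 6 libraries.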
